A study of Mus musculus with 18 samples.

How the data were processed

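RNA of 18 samples from Ppt1 knockout and wild-type mice was hybridised to 1 Affymetrix mouse array each, and genotype, age and sex were taken from the labels. Replicates were numbered in the order of their sample records, since the labels give each sample a number of its own. The deposited values are probe set intensities on a linear scale. Software, version and scaling method behind these intensities are not given in the sources used here. In the deposited values themselves, the mean without the lowest and highest 2% of probe sets was 150 on every array, so the arrays had been scaled to each other. The array medians spanned 0.069 on the log2 scale, below the limit of 0.5 set for further normalization, and the values were used as deposited. No 2 arrays held identical values. The depth of an array is its number of probe sets, and precision is limited by 3 arrays in a group.

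Values were analysed as log2(signal + 16), so a fold change is on that scale and understates the change of dim genes. The 64 control probe sets and the 40% of probe sets with the lowest mean were left out, which left 27025 probe sets with a mean log2 value of at least 5.36. Of those tested, 22966 had 1 gene symbol in the platform annotation, 571 had several and 3488 had none. Genes were named only from probe sets with 1 symbol. Over the whole table, 34958 probe sets had 1 symbol, of which 34754 matched a gene of the RefSeq table of assembly GRCm38.p6 by Entrez identifier, 204 did not, and 0 symbols needed an update. That table was used only for names and for which genes neighbour each other.

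A linear model with the 6 groups of genotype and age and an additive term for sex was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a variance trend). The contrasts were knockout minus wild type as the mean over ages and at 3, 5 and 8 months, the effect at 8 months minus that at 3 months, and 8 minus 3 months within each genotype. P-values were adjusted by the Benjamini-Hochberg method over the tested probe sets, with a threshold of 0.05, and the tests were two-sided. An error after a log2 change is the standard error of the fit, and an error after a signal is the SD over arrays. Where all arrays of a group lay at or below the 95th percentile of the 27 bacterial control probe sets of the array, the fold is given as a lower bound, "at least N-fold". It sets the mean of the brighter group against the mean of, per array, the higher of that percentile and the measured signal.

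The 33 gene lists covered astrocytes, microglia and macrophages, complement, interferon response, antigen presentation, lymphocytes, lysosome, palmitoylation cycle, cholesterol biosynthesis, lipid transport, fatty acids, endoplasmic reticulum stress, oxidative stress, oxidative phosphorylation, GABAergic and excitatory neurons, presynaptic and postsynaptic proteins, immediate early genes, neuropeptides, oligodendrocytes, precursors and cell cycle, endothelium, choroid plexus, meninges, blood, cochlea, cerebellum, striatum, thalamus with hypothalamus and hindbrain, circadian clock, glucocorticoid response and the genes near Ppt1. They were tested with limma's camera on 1 probe set per gene, the one with the highest mean (12496 genes), with a preset correlation of 0.01 and beside it an estimated one, adjusted over the lists of a comparison. Members were also counted after adjustment over the list alone. The lymphocyte list had 3 measured genes, under the minimum of 5, and was not tested. Some genes stand in more than 1 list.

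The genes named were Ppt1, up to 12 higher and 12 lower genes with the largest change that passed in a comparison (in the same direction at every age for the mean), and up to 4 members per list with the smallest p that passed. For changes with age, the rule took up to 5 genes each way and 2 per list. A gene named for its large change was given from its probe set with the largest change, and a list member from its brightest. Genes expressed from the sex chromosomes in a sex-specific way were not named as results. The groups, the lists, this rule, the model and the other settings to be tried were fixed before the data were examined.

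Alternatives were quantile normalization, median centring, a pseudocount of 1 or 64, no filter and a filter of the lowest 60%, no sex term, a variance model without trend or robust, array weights, 1 probe set per gene, only the groups compared, and each array left out in turn. The fit with only the groups compared had no sex term and took its spread from those groups alone. For the lists, an estimated correlation and all probe sets were tried as well. The model was tested on simulated data with 50 changed probe sets of each size among the 27025. The noise was independent between probe sets and had the same spread in all 6 groups. For the mean over ages it recovered 72% of those changed by 0.5 on the log2 scale and 94% of those changed by 1. At 3 months it recovered 30% and 74% of these sizes, and for the 8 minus 3 months difference 4% and 46%. False calls were 14 of 197 for the mean over ages, 10 of 160 at 3 months and 5 of 127 for the difference. The 8-month knockout arrays differed from each other more than those of other groups, so these shares need not hold where they enter. Single values between groups of arrays were compared by exact permutation within ages over 8000 arrangements. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No genome sequence was used.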

Results

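The study profiled RNA from mice that lack Ppt1 and from wild-type mice at 3, 5 and 8 months of age. Ppt1 encodes palmitoyl-protein thioesterase 1, a lysosomal enzyme that removes palmitate from proteins, and its loss in people causes infantile neuronal ceroid lipofuscinosis, a neurodegenerative storage disease. The labels name the source of the RNA with both "brain" and "cochlea" and do not say which part was dissected. Each of the 6 groups of genotype and age held 3 arrays. Every group had 1 male and 2 females except the knockout at 8 months, which had 2 males and 1 female. The labels do not say that the 3 arrays of a group come from separate mice, so the p-values measure the spread between these samples, which may be partly technical. The array medians of the signal lay between 43.17 and 46.09, and the number of arrays limits the precision. Xist, Eif2s3y and Kdm5d matched the labelled sex on 18 of 18 arrays.

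Ppt1 itself was reduced in every knockout sample. Its brightest probe set read 12.9 ± 7.66 in the knockout and 595 ± 29.3 in the wild type (signal, SD, n = 9 each), and no knockout array (highest 23.4) came near a wild-type array (lowest 543). The log2 change was -4.46 ± 0.12 (standard error), with an adjusted p of 1.27e-16. Of the knockout arrays 5 of 9 lay at or below the background set by the bacterial control probe sets, 3 of 3 at 3 months and 2 of 3 at 5 months. The signal was therefore at least 19-fold lower over all ages and at least 21.5-fold lower at 3 months. The knockout signal was 8.43 ± 5.52 at 3 months, 10.7 ± 9 at 5 months and 19.6 ± 4.47 at 8 months (SD, n = 3 each). Another Ppt1 probe set fell by 3.57 ± 0.15 on the log2 scale (adjusted p 3.36e-13) and a dimmer one fell by 0.78 ± 0.15 (adjusted p 0.00157). A further Ppt1 probe set differed by 0.11 ± 0.12 (adjusted p 0.611), and the last was too dim to test. Where these probe sets lie relative to the disrupted part of the gene is not known here, so the probe sets that moved little say nothing about the labels.

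Genotype separated the arrays. Along the main principal component, which held 24.2% of the variance, the 9 wild-type arrays of all ages lay between -18.9 and -11.6. The knockout arrays lay between -1.9 and -1.4 at 3 months and between 11.1 and 17.6 at 5 months. At 8 months replicates 1 and 2 lay at 50.7 and 45.6, while replicate 3 lay at 9.9, below the 5-month knockouts. The mean correlation with the other arrays of the group was 0.9669, 0.9694 and 0.9614 for the 8-month knockout replicates 1, 2 and 3, and at least 0.979 elsewhere. The 5-prime to 3-prime ratio of actin, a sign of RNA quality, averaged 0.475 in the knockout and 0.4951 in the wild type (n = 9 each, exact permutation test within ages, two-sided p = 0.271). At 8 months it lay between 0.432 and 0.482 in the knockout, below the 0.501 to 0.525 of the wild type. The same ratio of Gapdh lay between 1.22 and 1.246, below 1.258 to 1.349. At 3 months the mean actin ratio was 0.5293 in the knockout and 0.504 in the wild type, with overlapping ranges. The spike-in control probe sets of the 8-month knockout replicate 3 lay on average 0.433 on the log2 scale above their medians over all arrays, against -0.202 to 0.202 on the other arrays.

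**Figure D1:**
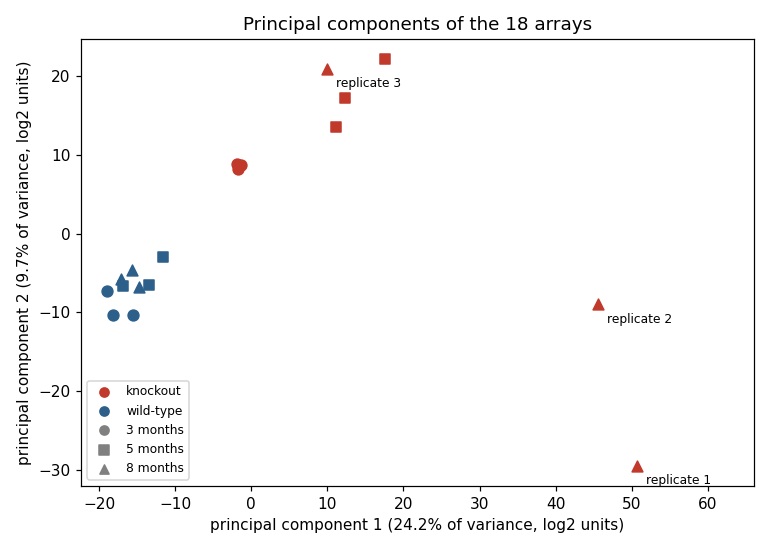
Each point is 1 of the 18 arrays, placed by its scores on principal component 1 (horizontal, log2 units) and principal component 2 (vertical, log2 units), with colour for genotype and shape for age. The wild-type arrays lie together at the left, and the 8-month knockout replicates 1 and 2, at 50.7 and 45.6, lie far to the right of replicate 3 at 9.9.

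The comparison over all ages asked which genes depend on Ppt1 regardless of age, as the mean of the 3 within-age differences (n = 9 each). Genes of reactive glia led the increase. Gfap, the intermediate filament of reactive astrocytes, rose by 2.68 ± 0.09 on the log2 scale (6.39-fold) at its probe set with the largest change. Serpina3n, a protease inhibitor of reactive astrocytes, rose by 3.16 ± 0.14 (8.97-fold). Clec7a (2.94 ± 0.16), the lysozymes Lyz1 (2.83 ± 0.17) and Lyz2 (2.47 ± 0.16), Lgals3 (2.59 ± 0.17) and Gpnmb (2.55 ± 0.21), all genes of activated microglia and macrophages, rose as well. Clec7a lay at background on 4 of 9 wild-type arrays (2 of 3 at 3 months). Cst7, a cystatin of the same cells, was at background in the wild type and at least 3.84-fold higher in the knockout. In all, 3418 of 27025 probe sets passed an adjusted p of 0.05, 1790 higher (1226 genes) and 1628 lower (1143 genes), but 110 of the higher and 13 of the lower ones changed 2-fold or more.

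Among the gene lists, 34 of 40 measured microglia and macrophage genes rose and 1 fell, with a median log2 change of 1.08 (adjusted p 1.36e-39). Tyrobp, a signalling adaptor of microglia, rose by 1.77 ± 0.08 and Mpeg1 by 2.17 ± 0.11. Of 27 astrocyte genes 22 rose and none fell (median 0.56, adjusted p 2.46e-26), among them the water channel Aqp4 (0.98 ± 0.06). Interferon response genes rose in 27 of 28 cases (median 0.89, adjusted p 5.52e-38), led by Cxcl10, a chemokine at background on 2 of 9 wild-type arrays (2.23 ± 0.15), Gbp6 (1.92 ± 0.13) and Lgals3bp (1.62 ± 0.08). The antigen presentation genes H2-K1 (1.45 ± 0.06) and B2m (1.23 ± 0.05) stood among 10 of 14 that rose (median 0.6, adjusted p 1.69e-16). The complement genes C1qa (1.39 ± 0.08) and C1qb (1.23 ± 0.08) stood among 8 of 12 (median 0.71, adjusted p 4.44e-10). Adjusted over the list alone, the numbers higher were 34, 22, 28, 13 and 8 in these 5 lists, in the order given. With an estimated correlation the adjusted p was 0.0042, 0.0035, 0.00214, 0.00214 and 0.0035 in the same order, so all 5 calls held.

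Lysosomal genes other than Ppt1 rose with the glial genes. Of 55 measured, 29 rose and 1 fell (31 and 1 adjusted over the list alone), with a median of 0.23 and an adjusted p of 6.22e-20 (adjusted p = 0.00937 with an estimated correlation). They included Cd68, a lysosomal protein of macrophages (1.78 ± 0.12), the protease Ctsd (1.04 ± 0.06) and Grn, the progranulin gene (0.86 ± 0.06). Lipid transport genes behaved alike, with 11 of 20 higher and 1 lower over all probe sets and over the list alone (median 0.32, adjusted p 1.68e-08, adjusted p = 0.0042 with an estimated correlation), led by the cholesterol exporter Abca1 (0.95 ± 0.09) and Clu (0.55 ± 0.04). Of 26 oxidative and stress response genes 11 rose and 1 fell (15 and 1 adjusted over the list alone, median 0.16, adjusted p 2.12e-06, adjusted p = 0.0042 with an estimated correlation), including Hmox1, which degrades haem and lay at background on 1 of 9 wild-type arrays (1.03 ± 0.15).

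Neuronal genes were lower by smaller amounts. Of 28 excitatory neuron genes 13 fell and none rose (18 adjusted over the list alone), with a median of -0.19 and an adjusted p of 3.83e-08 (adjusted p = 0.002 with an estimated correlation). Tbr1, a transcription factor of deep cortical neurons, fell by 0.63 ± 0.08, and Nrgn, a postsynaptic calmodulin-binding protein, fell by 0.38 ± 0.05. Of 28 GABAergic interneuron genes 5 fell (8 adjusted over the list alone, median -0.14, adjusted p 3.86e-05, adjusted p = 0.0133 with an estimated correlation), among them the peptide genes Vip (-0.48 ± 0.06) and Cck (-0.42 ± 0.06). Of 15 striatal genes 6 fell (10 adjusted over the list alone, median -0.17, adjusted p 0.000131, adjusted p = 0.00951 with an estimated correlation), including the phosphatase Ptpn5 (-0.23 ± 0.05). The microglia and astrocyte lists moved the other way in the same samples, by medians of 1.08 and 0.56, and these are values of a mixed tissue.

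Another 11 lists passed with the preset correlation and not with an estimated one. Presynaptic genes (11 of 29 lower, median -0.11, adjusted p 1.27e-05) included Cplx2 (-0.27 ± 0.04), with an adjusted p = 0.0694 with an estimated correlation. Immediate early genes (12 of 28 higher and 1 lower, median 0.31, adjusted p 1.21e-06) included Fos (1.42 ± 0.16) and Dusp1 (0.71 ± 0.1), also with adjusted p = 0.0694 with an estimated correlation. Meningeal and fibroblast genes (15 of 24 higher, median 0.37, adjusted p 2.73e-10) gave adjusted p = 0.0605 with an estimated correlation, and endothelial genes (5 of 26 higher, median 0.12, adjusted p 0.000605) gave adjusted p = 0.0694, with Vcam1, an adhesion molecule, at 0.76 ± 0.07. Glucocorticoid response genes (6 of 22 higher and 1 lower, median 0.23, adjusted p 0.000203) gave adjusted p = 0.336 with an estimated correlation. Postsynaptic genes (7 of 19 lower and 1 higher, median -0.13, adjusted p 0.000878) gave 0.126, cerebellar genes (5 of 19 lower, median -0.16, adjusted p 0.000652) gave 0.171 and oxidative phosphorylation genes (5 of 39 lower, median -0.06, adjusted p 9.4e-05) gave 0.223 as adjusted p with an estimated correlation. Cholesterol biosynthesis genes (4 of 20 lower, median -0.08, adjusted p 0.00609) gave 0.173, fatty acid genes (8 of 29 higher, median 0.1, adjusted p 0.000652) gave 0.0694, and genes of the palmitoylation cycle (3 of 22 lower, median -0.08, adjusted p 0.0161) gave 0.0694 as adjusted p with an estimated correlation. Adjusted over the list alone, the counts were 13 lower for presynaptic genes, 14 higher and 1 lower for immediate early genes, 19 higher for meningeal genes, 5 higher for endothelial genes, 10 higher and 1 lower for glucocorticoid genes, 10 lower and 1 higher for postsynaptic genes, 5 lower for cerebellar genes, 6 lower for oxidative phosphorylation, 4 lower for cholesterol biosynthesis, 10 higher and 1 lower for fatty acid genes, and 5 lower and 1 higher for the palmitoylation cycle.

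The remaining 10 lists tested did not pass over all ages. These were oligodendrocyte and myelin genes (adjusted p 0.796, 4 of 26 higher and 2 lower), precursors and cell cycle (0.0624), endoplasmic reticulum stress (0.421), neuropeptides (0.0785), choroid plexus and ependyma (0.423), blood (0.827, 6 genes measured), cochlea and inner ear (0.298), thalamus, hypothalamus and hindbrain (0.48), circadian clock (0.0967) and the genes near Ppt1 (0.669). Of 31 cochlear genes on the list 10 were bright enough to be measured.

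A few genes changed by a similar size at every age. Cap1, which encodes an actin-binding protein and is the next gene to Ppt1 on the chromosome, rose by 2.81 ± 0.08 (7.02-fold, adjusted p 1.37e-16), with signals above every wild-type array on 9 of 9 knockout arrays. Ndufs5, a subunit of respiratory complex I that lies 16 genes from Ppt1, fell by 1.13 ± 0.04 (adjusted p 1.9e-14), and 9 of 9 knockout arrays lay below every wild-type array. Also lower were Gabra2, a GABA receptor subunit (-1.2 ± 0.08), Wdfy1 (-1.29 ± 0.1), Nnt, the mitochondrial transhydrogenase (-0.79 ± 0.08), and Erdr1 (-1.59 ± 0.09). All 10 tested probe sets of these 4 genes fell, 1 of the Erdr1 probe sets by 0.49 ± 0.15 with 5 of 9 knockout arrays below every wild-type array. The change of that probe set was uneven, at -0.41, -0.92 and -0.13 at 3, 5 and 8 months. The other probe sets of Wdfy1 changed by -0.98 ± 0.1 and -1 ± 0.08. Mid1 was lower over the ages (-2.11 ± 0.26), but at 5 months it did not pass (-1.27 ± 0.44, adjusted p 0.165), and 1 of 9 knockout arrays lay below every wild-type array. Of the 58 measured genes among the 50 on each side of Ppt1, 11 passed (19%, exact Clopper-Pearson 95% interval 9.9 to 31.4%) against 14.8% of the 12437 other genes (Fisher's exact test, two-sided p = 0.355). Leaving out the 8-month knockout replicates 1 and 2, an alternative chosen after seeing the data, gave 2070 probe sets in place of 3418, and the cholesterol biosynthesis and cerebellar lists no longer passed (adjusted p 0.233 and 0.104).

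At 3 months, the youngest age, interferon and microglial genes were already higher in the knockout (n = 3 each). Clec7a rose by 2.6 ± 0.28, Cxcl10 by 2.17 ± 0.26 and Ifit1, an interferon-induced gene, by 1.78 ± 0.26, while Gfap rose by 1.85 ± 0.15 (3.61-fold). Of 28 interferon genes 21 rose (28 adjusted over the list alone, median 1, adjusted p 2.65e-50, adjusted p = 0.00124 with an estimated correlation), and of 40 microglial genes 15 rose (26 adjusted over the list alone, median 0.76, adjusted p 1.24e-35, adjusted p = 0.00982 with an estimated correlation). Antigen presentation (6 of 14 higher, 8 adjusted over the list alone, median 0.62, adjusted p 8.6e-20, adjusted p = 0.00124 with an estimated correlation) and complement (3 of 12 higher, 5 adjusted over the list alone, median 0.48, adjusted p 1.66e-08, adjusted p = 0.00667 with an estimated correlation) rose too. Of 27 astrocyte genes 5 rose (11 higher and 1 lower adjusted over the list alone), with a median of 0.23 (adjusted p 1.06e-07), and the list did not pass with an estimated correlation (adjusted p = 0.0801). Excitatory neuron genes were lower by a median of -0.14 (1 of 28, or 6 adjusted over the list alone, adjusted p 1.11e-05, adjusted p = 0.00338 with an estimated correlation), and Vip fell by 0.57 ± 0.1. Lysosomal genes (7 of 55 higher, 16 higher and 1 lower adjusted over the list alone, median 0.2, adjusted p 1.92e-12) gave adjusted p = 0.0621 with an estimated correlation.

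Besides Ppt1, the genes with the largest decreases at 3 months were Mid1 (-2.61 ± 0.44), Erdr1 (-1.44 ± 0.16), Wdfy1 (-1.3 ± 0.17) and Gabra2 (-1.27 ± 0.13), and the myelin gene Mal fell by 0.71 ± 0.11. In all, 258 probe sets passed, 184 higher and 74 lower. The call count was 123, 128 or 154 without knockout replicate 1, 2 or 3 of this age, 127 or 153 without wild-type replicate 2 or 3, and 444 without replicate 3 of the 8-month knockout, which enters through the shared estimate of the spread.

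At 5 months astrocyte, microglial and interferon genes were higher in the knockout. Gfap was 2.83 ± 0.15 higher (7.11-fold). Its brighter probe set was 2.5 ± 0.11 higher, with signals of 4010 ± 321 in the knockout and 697 ± 34.1 in the wild type (SD, n = 3 each), and Serpina3n was 3.5 ± 0.24 higher (11.3-fold). Of 27 astrocyte genes 16 rose (20 adjusted over the list alone, median 0.52, adjusted p 4.24e-25, adjusted p = 0.00426 with an estimated correlation), and of 40 microglial genes 25 rose (32 higher and 1 lower adjusted over the list alone, median 0.92, adjusted p 9.68e-39, adjusted p = 0.00603 with an estimated correlation). Interferon genes rose in 20 of 28 cases (26 adjusted over the list alone, median 1.03, adjusted p 2.21e-39, adjusted p = 0.00177 with an estimated correlation). Lysosomal genes rose in 20 of 55 (27 adjusted over the list alone, median 0.3, adjusted p 3.9e-18, adjusted p = 0.0163 with an estimated correlation), with Cd68 at 2.1 ± 0.21 and Ctsd at 1.07 ± 0.11. Excitatory neuron genes (2 of 28 lower, 6 adjusted over the list alone, median -0.22, adjusted p 1.09e-06, adjusted p = 0.00177 with an estimated correlation) included Gria2, an AMPA receptor subunit (-0.3 ± 0.06). Striatal genes (2 of 15 lower, 4 adjusted over the list alone, median -0.2, adjusted p 0.000396, adjusted p = 0.0163 with an estimated correlation) included the phosphodiesterase Pde10a (-0.73 ± 0.12).

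In all, 595 probe sets passed at 5 months, 442 higher and 153 lower, and S100a4, which encodes a calcium-binding protein, was at least 3.48-fold higher against a wild type at background. The call count was 294 or 380 without knockout replicate 1 or 2 of this age, 350 without wild-type replicate 2 and 930 without replicate 3 of the 8-month knockout.

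At 8 months glial, lysosomal and lipid transport genes were higher in the knockout and cholesterol biosynthesis genes lower. Gpnmb, a glycoprotein of lipid-laden macrophages, was 4.33 ± 0.37 higher (20.1-fold), with signals of 1090 ± 687 against 32.4 ± 6.82 in the wild type (SD, n = 3 each). Without knockout replicate 3 the difference was 5. The log2 SD of Gpnmb was 1.31 in the 8-month knockout and 0.12 to 0.46 in the other groups. Its error, from the spread shared by all groups, therefore understates the variation at this age. Serpina3n was 4.12 ± 0.24 higher (17.4-fold) and Gfap, at its probe set with the largest change, 3.34 ± 0.15 higher (10.1-fold). The log2 SD of Serpina3n was 0.74 in the 8-month knockout and at most 0.35 in the other groups, so its error has the same limit. In replicate 3 the signals of Gpnmb (293.6), Serpina3n (1039) and the brighter Gfap probe set (4122) lay within the range of the 5-month knockout arrays (239.9 to 336.3, 718.7 to 1041 and 3692 to 4333). Those of replicates 1 and 2 lay above it. The effects at 8 and 5 months were not tested against each other. Vim, an intermediate filament of reactive astrocytes (2.25 ± 0.19), Osmr, the oncostatin M receptor (2.66 ± 0.25), the metallothioneins Mt1 (1.31 ± 0.14, after 0.58 ± 0.14 at 5 months, adjusted p 0.0297) and Mt2 (1.68 ± 0.19) and the small heat shock protein gene Cryab (0.73 ± 0.08) rose as well. Among the genes that fell were Dbp, a clock-controlled transcription factor (-1.24 ± 0.18), Fdft1, squalene synthase (-0.49 ± 0.08), and the excitatory neuron gene Lmo4 (-0.52 ± 0.07).

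By list, 29 of 40 microglial genes rose and 1 fell, over all probe sets and over the list alone (median 1.26, adjusted p 4.72e-30, adjusted p = 0.0123 with an estimated correlation), and 22 of 27 astrocyte genes rose (24 adjusted over the list alone, median 0.74, adjusted p 1.79e-29, adjusted p = 0.00542 with an estimated correlation). Lysosomal genes rose in 28 of 55 cases and 1 fell (32 and 1 adjusted over the list alone, median 0.4, adjusted p 2.31e-15, adjusted p = 0.0203 with an estimated correlation). Lipid transport genes rose in 11 of 20 (13 higher and 1 lower adjusted over the list alone, median 0.41, adjusted p 5.36e-09, adjusted p = 0.00646 with an estimated correlation), with Abca1 at 1.52 ± 0.15. Cholesterol biosynthesis genes fell in 11 of 20 cases (14 adjusted over the list alone, median -0.42, adjusted p 8.77e-09, adjusted p = 0.0159 with an estimated correlation). Glucocorticoid response genes rose in 16 of 22 (21 adjusted over the list alone, median 1.02, adjusted p 1.32e-15), with adjusted p = 0.0646 with an estimated correlation, and the list median per array, against wild type of the same age, was 1.68, 0.7 and 0.57 in replicates 1, 2 and 3. Of 28 excitatory neuron genes 10 fell and 1 rose (10 and 2 adjusted over the list alone, median -0.21, adjusted p 5.64e-05, adjusted p = 0.00646 with an estimated correlation). Oligodendrocyte genes did not pass (median 0.07, adjusted p 0.203).

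In all, 3147 probe sets passed at 8 months, 1550 higher and 1597 lower, 292 and 55 of them by 2-fold or more. The call count was 1266 without knockout replicate 2, 1901 without knockout replicate 1, 1744 or 1976 without wild-type replicate 1 or 2, and 5370 without knockout replicate 3. Without knockout replicates 1 and 2 together, an alternative chosen after seeing the data that leaves 1 knockout array assumed to vary like the others, 497 probe sets passed, and 62 of the 124 named genes of this age kept their call. With only the groups compared, which takes the spread from those groups alone, 91 of the 124 named genes of this age kept their call. The 5-prime to 3-prime ratios of actin and Gapdh were lower on all 3 knockout arrays of this age than on the wild-type arrays.

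**Figure D2:**
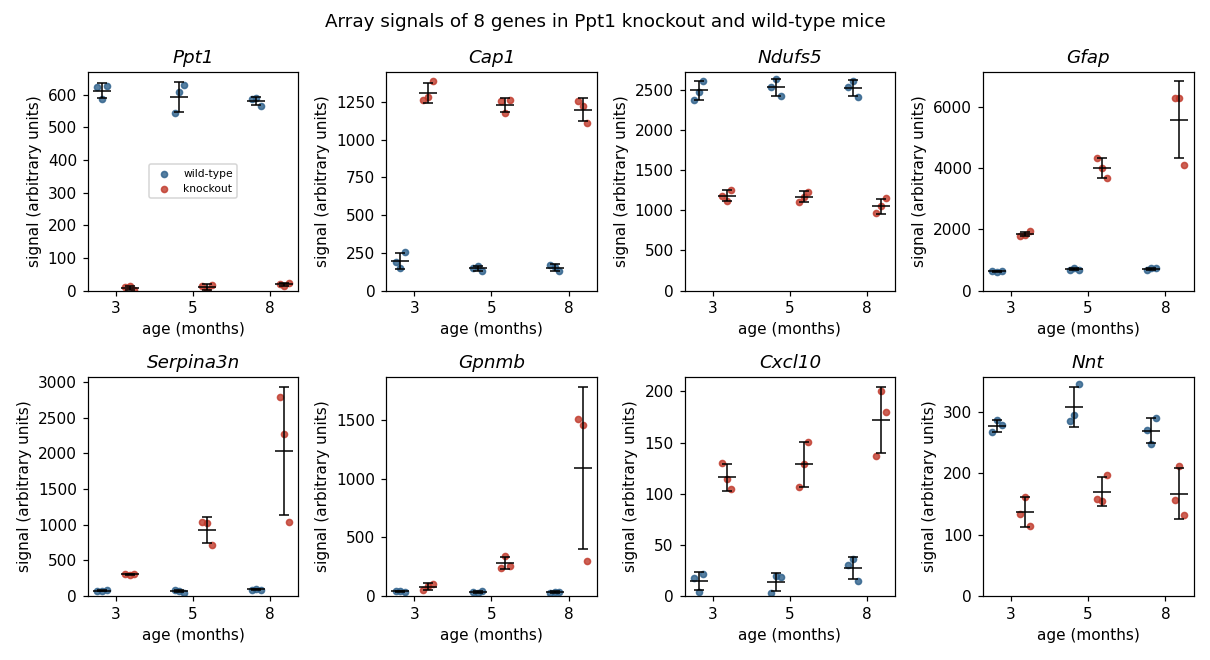
Signals (arbitrary units, linear axes from 0) of 8 genes on each array by age in months, with wild type in blue, knockout in red, and black bars for the mean and SD of each group of 3. Cap1, Ndufs5, Ppt1 and Nnt differed by a similar size at each age, while Gfap reached 1850 at 3 months, 4010 at 5 months and 5580 at 8 months in the knockout.

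Set side by side, most probe sets that passed at 2 ages changed in the same direction. Each age had its own wild-type arrays. Across 27025 probe sets, which are not independent replicates, Pearson's r of the log2 changes was 0.40 between 3 and 5 months (Spearman's rho 0.249), 0.283 between 3 and 8 months (0.183) and 0.462 between 5 and 8 months (0.32). Of the 173 probe sets that passed at both 3 and 5 months, 173 had the same sign, and 143 were higher at both ages where independent lists would share 3. Likewise 176 of 180 shared by 3 and 8 months and 425 of 426 shared by 5 and 8 months had the same sign. All ages share 1 estimate of the spread per probe set, so calls at 2 ages are not independent. The 3 expected of independent lists is therefore only a rough reference. Those of opposite sign at 3 and 8 months, looked up after their values were seen, were probe sets of Sgk1, Mfsd2a, Slc2a1 and Gm19439, each lower at 3 months and higher at 8 months. Mfsd2a, a lipid transporter of the endothelium, went from -0.93 ± 0.21 at 3 months to 0.83 ± 0.21 at 8 months. Slc2a1, a glucose transporter, went from -0.58 ± 0.14 to 0.68 ± 0.14. The differences of both genes passed (adjusted p 0.00705 and 0.00376), and Mfsd2a lies 2 genes and Slc2a1 42 genes from Ppt1. Of the probe sets higher at 8 months, 75.9% were above 0 at 3 months and 85.6% at 5 months, and of those lower, 68.8% and 83.7% were below 0. At all 3 ages 127 probe sets of 88 genes were higher and 26 of 16 genes were lower, including Gfap, Serpina3n, Clec7a, Cxcl10 and Cap1 among the higher and Ndufs5, Gabra2, Wdfy1 and Erdr1 among the lower.

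**Figure D3:**
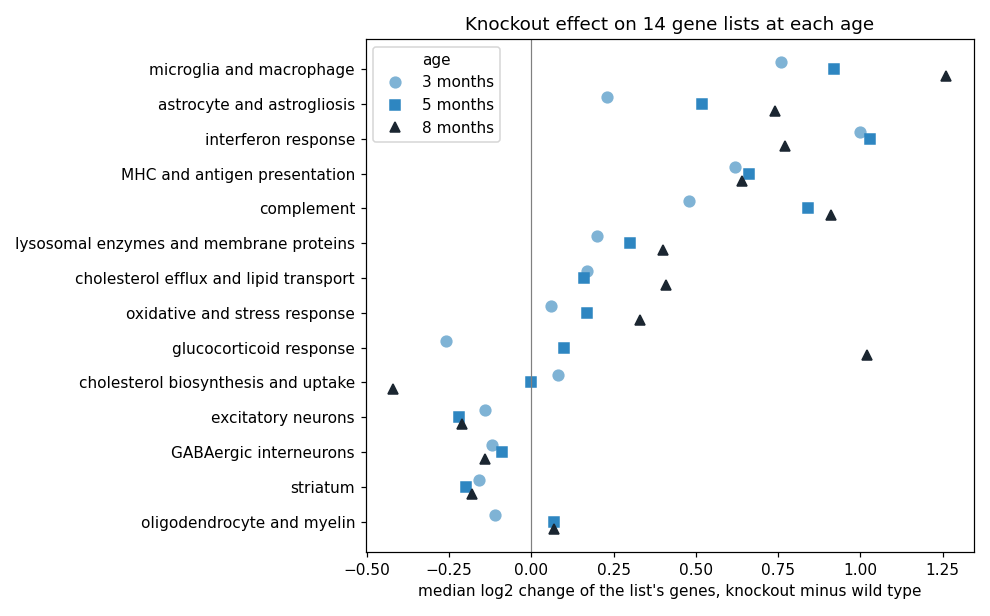
Median log2 change of the measured genes of 14 lists, knockout minus wild type, at 3 months (circles), 5 months (squares) and 8 months (triangles), with 0 as no change. The astrocyte median was 0.23, 0.52 and 0.74 at the 3 ages, while the interferon median was 1, 1.03 and 0.77.

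The difference between the knockout effects at 8 and 3 months tested which changes differed with age. Astrocyte genes gained, with 12 of 27 showing a larger effect at 8 months (20 adjusted over the list alone, median difference 0.58, adjusted p 8.94e-24, adjusted p = 0.0104 with an estimated correlation). The effect on Gfap was 1.39 ± 0.16 larger on the log2 scale at its brighter probe set, that on Serpina3n 2.25 ± 0.34 larger, and that on Gpnmb 3.59 ± 0.52 larger (4.25 without the 8-month knockout replicate 3). Glucocorticoid response genes had a median difference of 1.29 (12 of 22 higher, 20 higher and 1 lower adjusted over the list alone, adjusted p 8.94e-24), with adjusted p = 0.0586 with an estimated correlation. Among them Sgk1, a glucocorticoid-induced kinase, differed by 2.41 ± 0.31, from -1.18 ± 0.22 at 3 months. From 3 to 8 months it rose by 1.19 ± 0.22 in the knockout and fell by 1.21 ± 0.22 in the wild type. In the ageing wild type the median of this list was -0.56 (1 of 22 lower, 12 adjusted over the list alone, adjusted p 2.21e-16, adjusted p = 0.254 with an estimated correlation). Cholesterol biosynthesis genes moved down (4 of 20, or 14 adjusted over the list alone, median difference -0.5, adjusted p 1e-12, adjusted p = 0.0104 with an estimated correlation), with Fdft1 at -0.58 ± 0.11. Oxidative and stress response genes moved up (5 of 26, or 8 adjusted over the list alone, median difference 0.23, adjusted p 6.2e-08, adjusted p = 0.0104 with an estimated correlation), with Mt1 at 1.53 ± 0.2 and Mt2 at 1.98 ± 0.27. The interferon list, by contrast, had a median difference of -0.17 (adjusted p 0.0143, adjusted p = 0.449 with an estimated correlation), and it did not pass without the 8-month knockout replicate 1 (0.111), the 3-month wild-type replicate 3 (0.0806) or the 8-month wild-type replicate 2 (0.104). Excitatory neuron genes did not pass in this test (median -0.12, adjusted p 0.292).

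In all, 282 probe sets had a different knockout effect at 8 months, 194 upward and 88 downward. The call count was 104, 98 or 118 without 3-month knockout replicate 1, 2 or 3, 44 or 128 without 3-month wild-type replicate 2 or 3, and 66, 133 or 96 without 8-month wild-type replicate 1, 2 or 3. It was 143 or 111 without 8-month knockout replicate 1 or 2, 1967 without replicate 3, 85 without replicates 1 and 2 together, and 0 in limma without a variance trend (3642 at an unadjusted p under 0.05). Of the 55 named genes, 14 kept their call without replicates 1 and 2, Fdft1 not among them. With only the groups compared, which takes the spread from those groups alone, 32 of the 55 named genes kept their call. The actin and Gapdh 5-prime to 3-prime ratios were lower in the knockout than in the wild type on all 3 arrays at 8 months and not at 3 months.

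Ageing from 3 to 8 months was compared within each genotype. In the wild type few genes passed (n = 3 each): Neat1, a long noncoding RNA, rose by 0.74 ± 0.12 (adjusted p 0.0278) and Pisd-ps3 by 0.8 ± 0.11 (adjusted p 0.0102), while Col1a1, a collagen gene at background in the older mice, was at least 2.33-fold lower. Sgk1 fell by 1.21 ± 0.22 (adjusted p 0.0494), from a signal of 2120 ± 43 to 915 ± 172 (SD). Its call was lost in 13 of the 18 fits with 1 array left out. In the knockout Lyz1 rose by 3.4 ± 0.39, Gpnmb by 3.39 ± 0.37, Lyz2 by 2.63 ± 0.28 and the brighter Gfap probe set by 1.57 ± 0.11, the complement gene C1qa rose by 0.87 ± 0.15, and Gabrd, a GABA receptor subunit, fell by 0.55 ± 0.1. The log2 SD in the 8-month knockout was 1.42 for Lyz1, 1.31 for Gpnmb and 0.99 for Lyz2. In the other groups it was at most 0.54, 0.46 and 0.35. The errors of these genes, from the spread shared by all groups, therefore understate the variation at 8 months.

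In all, 8 probe sets passed in the ageing wild type, 6 higher and 2 lower, with 1819 at an unadjusted p under 0.05 where 1351 are expected by chance, and 1519 passed in the ageing knockout, 784 higher and 735 lower. The wild-type count was 0 without wild-type 3-month replicate 1 or 2 or 8-month replicate 1 or 3 in limma (1671, 1542, 1446 and 1698 at an unadjusted p under 0.05), so none of these genes kept its call in those fits, 3 without 8-month replicate 2 and 5 without 3-month replicate 3, neither with Neat1 or Col1a1, and 5 without wild-type 5-month replicate 1, knockout 3-month replicate 2 or 3 or knockout 5-month replicate 2. It was 29, 20 or 45 without 8-month knockout replicate 1, 2 or 3. The knockout count was 489, 667 or 766 without 3-month knockout replicate 1, 2 or 3, 587, 308 or 4302 without 8-month knockout replicate 1, 2 or 3, and 94 without its replicates 1 and 2 together, when 10 of the 51 named genes of the ageing knockout kept their call. Gfap, Gpnmb, Lyz1 and Lyz2 were not lost when any 1 array was left out, but the rise of Gpnmb was 4.06 without 8-month knockout replicate 3, and that of Lyz1 was 2.78 without replicate 2 and 4.11 without replicate 3. With only the groups compared, which takes the spread from those groups alone, 11 of the 51 named genes of the ageing knockout kept their call. Signs of RNA quality differed between the knockout ages. The actin 5-prime to 3-prime ratio lay between 0.507 and 0.542 at 3 months and between 0.432 and 0.482 at 8 months, and that of Gapdh between 1.345 and 1.394 and between 1.22 and 1.246. In the wild type both ratios had overlapping ranges (mean actin ratio 0.504 and 0.512, mean Gapdh ratio 1.343 and 1.297).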

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

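The tests in this part of why the 8-month knockout arrays differ were chosen only after the result was seen, except the slope of replicate 3, and the count over other splits was planned. The results below were singled out because the knockout effect at 8 months differed from that at 3 months in limma's test of the difference itself. This held for 282 probe sets. Of 100 splits of the samples, the real one included, 1 gave as many, and the highest of the others gave 133. The other splits mix arrays of different ages within a genotype, which widens the spread and can lower their counts. They therefore test whether age had any effect, not whether its effect differed between genotypes, and chance in the difference itself stays open.

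Among the lists, the median log2 difference between the ages was 0.58 for astrocyte genes, 1.29 for glucocorticoid response, -0.5 for cholesterol biosynthesis and 0.23 for oxidative and stress response. It was 0.47 for microglia, 0.21 for lysosomal genes, 0.25 for endoplasmic reticulum stress, 0.23 for lipid transport, 0.29 for meninges, 0.2 for neuropeptides, -0.33 for cerebellum, 0.23 for oligodendrocytes, 0.38 for complement and -0.17 for interferon response. With an estimated correlation 3 of these 14 lists passed, astrocytes, cholesterol biosynthesis and oxidative stress (adjusted p = 0.0104 each). The other 11 did not: lipid transport (adjusted p = 0.0579), glucocorticoid response (0.0586), neuropeptides (0.111), endoplasmic reticulum stress and complement (0.225 each), lysosomal genes and cerebellum (0.269 each), microglia and meninges (0.291 each), oligodendrocytes (0.31) and interferon response (0.449). Without the 8-month knockout replicates 1 and 2 the medians turned to -0.08 for meninges (adjusted p 0.898) and 0.04 for cerebellum (0.973), and neither passed. Then microglia (0.893), lysosomal genes (0.82), interferon response (0.82), complement (0.572) and oligodendrocytes (0.421) did not pass either. Against the 3-month wild type the glucocorticoid medians were 1.12, 0.18 and 0.01 in the 8-month knockout replicates and -0.69, -0.66 and -0.43 in the 8-month wild type, so part of the difference lies in low wild-type values.

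Among the genes that gained, the log2 difference (± standard error) was 3.59 ± 0.52 for Gpnmb, 3.41 ± 0.66 for Plin4, 3.27 ± 0.65 for Lcn2, 2.67 ± 0.64 for Cdkn1a, 2.54 ± 0.55 for Lyz1, 2.49 ± 0.39 for Hspb1, 2.41 ± 0.31 for Sgk1, 2.27 ± 0.52 for Homer1, 2.25 ± 0.34 for Serpina3n, 2.03 ± 0.42 for Hif3a, 2 ± 0.39 for Lyz2 and 1.98 ± 0.42 for Lgals3. It was 1.39 ± 0.16 for Gfap, 0.89 ± 0.14 for Aqp4, 1.5 ± 0.26 for Vim, 1.53 ± 0.2 for Mt1, 1.98 ± 0.27 for Mt2, 1.18 ± 0.18 for Cldn11, 1.26 ± 0.19 for Slc2a1, 1.76 ± 0.3 for Mfsd2a, 0.81 ± 0.16 for Ctsd and 1.06 ± 0.22 for Abca1. For Col1a1, at background in the 8-month wild type, the difference was at least 2.76-fold, with signals of 35.5 and 43.6 in the knockout and 51.4 and 6.7 in the wild type at 3 and 8 months. Among the genes that moved down it was -1.7 ± 0.31 for Serpinb1a, -1.58 ± 0.31 for Ptprk, -1.4 ± 0.31 for Abcd2, -1.29 ± 0.26 for Vamp1, -1.29 ± 0.21 for Stard4, -1.29 ± 0.26 for Ntrk2, -1.21 ± 0.28 for Btg2, -0.58 ± 0.11 for Fdft1, -1 ± 0.2 for Fdps, -0.53 ± 0.11 for Hmgcs1, -0.78 ± 0.17 for Sqle and -0.94 ± 0.22 for Pla2g15. The value for Ntrk2 rests on 1 of its 7 probe sets, and another of them moved up by 0.53 ± 0.12 (adjusted p 0.0338). In the 8-month wild type, Lcn2 was at background on 2 of 3 arrays and Plin4 on 1. The errors come from the spread shared by all groups. For Lyz1, Lyz2 and Serpina3n the log2 SD was 1.42, 0.99 and 0.74 in the 8-month knockout. In the other groups it was at most 0.54, 0.35 and 0.35, so the errors of these genes understate the variation. Without the 8-month knockout replicate 1 the difference was 1.77 for Cdkn1a and 2.61 for Plin4, and without replicate 2 it was 1.92 for Lyz1, which did not pass, and 3.11 for Homer1. Without replicate 3 it was 4.25 for Gpnmb, 4.12 for Plin4, 3.92 for Lcn2, 3.25 for Lyz1 and 1.64 for Homer1. The call was lost in 13 of the 18 fits with 1 array left out for Cdkn1a and in 10 each for Lyz1 and Homer1. Of the 55 genes named for this difference, 18 kept their call whichever array was left out, among them Gpnmb, Serpina3n, Sgk1, Gfap, Vim, Mt1 and Mt2.

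The 3 knockout arrays of 8 months differed from each other more than those of any other group. Degraded RNA as what sets replicates 1 and 2 apart from replicate 3 is argued against, since their actin 5-prime to 3-prime ratios, 0.482 and 0.448, lay within the 0.389 to 0.547 of the other 16 arrays and above the 0.432 of replicate 3. The slope of replicate 3 was 0.92 ± 0.019 (standard error, 173 probe sets), above the 0.8 set as the mark of a compressed scale. The error treats the probe sets as independent, which they are not, so the slope alone does not settle this. With slopes of 1.06 ± 0.04 and 1.14 ± 0.038 on replicates 1 and 2, and spike-in controls 0.433 above their medians on replicate 3, a technical difference of that array stays open. Acute stress before sampling may add to replicate 1, where the glucocorticoid list median was 1.68 against at most 0.57 on the other 16 arrays, while for replicate 2 the value of 0.7 lay too close to decide (SD of the wild-type arrays 0.1). Against the 3-month wild type the medians were 1.12, 0.18 and 0.01 in replicates 1, 2 and 3, so these values rest partly on low 8-month wild-type values. Of the 22 genes of this list 9 also stand in other lists, so it is not specific to stress. A difference in disease stage between the samples stays open and was not tested.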

How the results depend on the processing

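The alternative without the 8-month knockout replicates 1 and 2 was chosen only after the result was seen, and the others were planned. Apart from arrays left out in turn, 103 values of the main counts and correlations stayed within 1.5 times or the error and 40 did not, and no named gene turned its direction in any alternative. Ppt1 lay between -4.55 and -4.36 with 1 array left out. Median centring gave 1553 higher and 2042 lower over all ages, against 1790 and 1628.

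Without a filter, more probe sets were tested, and the 8 minus 3 months difference had 161 calls, ageing in wild type 2 and ageing in knockout 996. The correlations between ages were then 0.226, 0.147 and 0.29 (3 with 5, 3 with 8, 5 with 8 months), and 0.521, 0.378 and 0.567 with the lowest 60% left out, when ageing in wild type had 5 calls. Without a sex term that count was 3. Without a variance trend, limma called 134 at 3 months, 393 at 5 months, 690 in the ageing knockout, 0 for the 8 minus 3 months difference (3642 at an unadjusted p under 0.05) and 0 in the ageing wild type (1826). Array weights gave 668 at 3 months, 1204 for the difference, 51 for ageing wild type and 3006 for ageing knockout. With 1 probe set per gene fewer were tested, with 2023 calls over all ages, 1756 at 8 months, 171, 2 and 764 for the difference and the ageing comparisons. Only the groups compared gave 468 at 3 months (258 in the main fit) and 1185 at 8 months (3147). For the difference and the ageing comparisons this setting gave 175, 73 and 86 (282, 8 and 1519). It has fewer arrays, a spread from those groups alone and no sex term. Fewer arrays alone do not explain the rises at 3 months and in the ageing wild type. Except where fewer or more probe sets were used, the cause of these shifts was not tested.

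Without the 8-month knockout replicates 1 and 2, which leaves 1 array assumed to vary like the other groups, 2070 passed over all ages, 497 at 8 months, 85 for the difference and 94 in the ageing knockout. Of the calls made with all arrays, 1769, 350, 39 and 44 remained. The lists that passed for the difference fell from 14 to 8, and 2 turned direction, cerebellum (adjusted p 0.973) and meninges (0.898). The cause was not tested beyond the smaller number of arrays. With an estimated correlation 11, 5, 10, 11 and 3 lists passed over all ages, at 3, 5 and 8 months and for the difference, against 22, 23, 19, 22 and 14.

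With each array left out in turn, the counts ran from 2510 to 5028 over all ages, 123 to 444 at 3 months, 294 to 930 at 5 months, 1266 to 5370 at 8 months, 44 to 1967 for the difference, 0 to 45 in the ageing wild type and 308 to 4302 in the ageing knockout. The lowest came without knockout replicate 1 of that age at 3 and 5 months, knockout replicate 2 at 8 months and in the ageing knockout, and 3-month wild-type replicate 2 for the difference. In the ageing wild type 4 arrays gave 0 in limma (1446 to 1698 at an unadjusted p under 0.05). The highest came without the 8-month knockout replicate 3. At 3 and 5 months and in the ageing wild type this array enters only through the shared spread and the sex term. In the comparisons that hold it, the cause was not tested. No paired analysis was possible because the replicate numbers were given in record order and pair no samples. Signal over background limits dim genes, such as Cst7 in the wild type, to lower bounds.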

Other observations

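The tests in this part on single genes were chosen only after the result was seen, and the counts over other splits of the samples were planned. Several further genes differed over all ages. Prkcd, a kinase gene abundant in thalamus, fell by 0.59 ± 0.07 and Tnnt1 fell by 0.55 ± 0.11, while their list of thalamus, hypothalamus and hindbrain genes had 2 of 27 lower (median 0, mean -0.04, adjusted p 0.48). The clock genes Dbp (-0.59 ± 0.11) and Nr1d2 (-0.3 ± 0.05) were lower, with 5 of 18 clock genes lower and 2 higher (adjusted p 0.0967). Scg5 was lower (-0.23 ± 0.03) and Scg3, another gene of secretory granules, higher (0.25 ± 0.04), and the fibroblast genes Aebp1 and Fmod were 0.73 ± 0.09 higher each. These calls were kept whichever array was left out.

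Of the 100 splits of all samples for the mean over ages, 1, the real one, gave as many as 3418 probe sets, and the highest other gave 1018. The other splits mix the genotypes within an age, which widens the spread and can lower their counts. A share of 1 in 100, the smallest that these splits can give, argues against chance in the grouping without excluding it. The comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05. The real one, 1 of 10 in each, gave 258, 595 and 3147 at 3, 5 and 8 months against at most 0, 3 and 0 otherwise, 8 against 2 in the ageing wild type and 1519 against 128 in the ageing knockout.

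Cap1 was higher and Ndufs5 lower in the knockout, and both lie near Ppt1. Both effects were present at 3 months, and the largest gain to 8 months over their 3 probe sets was 0.27 ± 0.18 on the log2 scale, at Cap1, after 2.5 at 3 months. The 2 genes were taken up as ones that changed by a similar size at every age. The small gain is therefore no independent test against a response that grows with disease. A probe mismatch in the knockout's Cap1, which would lose signal, is argued against by 2 of 2 probe sets being higher. A mismatch in the wild type's Cap1 was not examined and stays open, as does a mismatch for Ndufs5, which has 1 probe set. Flanking DNA that changes many neighbours cannot be told apart from none, with 19% of 58 neighbours called (interval 9.9 to 31.4%) against 14.8% elsewhere. That share is of the mean over ages and misses effects that change sign. The neighbours Mfsd2a and Slc2a1, lower at 3 months and higher at 8 months, did not pass there (limma, adjusted p 0.532 and 0.892). An effect of the targeted locus on Cap1 and Ndufs5 may remain as a hypothesis.

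Gabra2, Nnt, Wdfy1 and Erdr1 were lower at every age. An even loss of excitatory neurons, of the size of their list median, falls short of the decreases of Gabra2, Nnt and Wdfy1. Their weakest of 8 probe sets changed by -0.78 ± 0.06, against an excitatory neuron median of -0.19 (SD 0.19). Such a loss stays open for Erdr1, where 1 of 2 probe sets changed by -0.49 ± 0.15. The genes were picked for large decreases, so lying below that median is no independent test against a loss of neurons. The median of a broad list would also not show the loss of a small group of neurons, which stays open. A variant under single probe sets is argued against as the whole cause for these 4 genes by 10 of 10 probe sets being lower. The 2 of Erdr1 changed by -1.59 ± 0.09 and -0.49 ± 0.15, so a variant that adds to the larger fall stays open there. A variant also stays open for Mkrn1, looked up beside them, where 2 of 6 were lower (-0.68 ± 0.05 and -0.25 ± 0.06) and 4 did not pass. A difference in strain background between the genotypes may be a candidate explanation, which cannot be told apart from the knockout, since genotype and any background coincide and the largest difference between 8 and 3 months over the 10 probe sets was 0.43, with none called. The labels used here do not give the strain.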
